A study of Arabidopsis thaliana with 12 samples.

How the data were processed

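Expression was measured on Affymetrix ATH1 arrays in roots of 7-day-old Arabidopsis thaliana Col-0 seedlings, 3 h after transfer to chitin oligomers, cellobiose, oligogalacturonides (OGs) or a control without elicitor. The labels give 3 biological replicates of each of the 4 groups, with 1 array each, so 12 arrays were used. Elicitor doses are not given in the sources used here. The series title and labels name the 3 h point, and a second time point that the design text mentions was not used here.

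The deposited values are log2 probe set intensities, normalized between arrays by the authors. Per the series design text the arrays were analysed with the GCRMA algorithm, and per the submitters' processing notes with Affymetrix Expression Console; which of them made the deposited values is not stated, and software versions are not given in the sources used here. The log2 scale was read from the values themselves, whose array medians lay between 6.30 and 6.41. Background subtraction and quantile scaling of this kind compress differences among dim probe sets and assume that most transcripts do not change, so a shift shared by all transcripts would not be visible. The number of arrays limits the precision.

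The value table held 22810 probe sets, of which 64 were the manufacturer's control probe sets and were kept out of the tests. The remaining 22746 were tested without a filter on brightness. In the probe annotation supplied with the series 13513 of these had exactly 1 gene, 503 had several and 8730 were not listed; of those with 1 gene, 13436 matched the current gene table. For gene-level results the probe set with the highest mean over all arrays stood for a gene, which gave 13356 genes. No gene with several probe sets had them called in opposite directions in any of the 6 comparisons. Genes are printed by the symbol or locus code of that annotation, and probe sets without a gene by their ID.

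Values were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), all 12 arrays in one linear model with 4 groups and the replicate number as a block, which left 6 residual degrees of freedom. The block follows the design text, in which ratios were taken within sample pairs and averaged over the 3 replicates. The 3 elicitors were each compared with the control and with each other, 6 contrasts in all, and a moderated F test covered the 4 groups together. P-values were adjusted by the Benjamini-Hochberg method within each contrast over all 22746 probe sets, and a probe set was called at an adjusted p under 0.05. Where the dimmer group's mean lay under log2 5, its arrays were raised to 5 and the size of a named gene's change is given as a lower bound, a choice made after the data had been seen. Other log2 changes are the fitted ones, given with the model's standard error (SE), group means with the SD of 3 arrays, and intervals at the 95 percent level from the same model. The labels name biological replicates. These p-values measure the spread between them that is left after the replicate block, pooled over the 4 groups.

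The genes named for each elicitor against the control are the 10 largest increases and the 10 largest decreases among genes that were called, moved the same way in all 3 replicate-number pairs and had a mean of at least log2 5 in the higher group. Between elicitors the 5 largest in each direction were named by the same rule, and in each gene list up to 4 called members with the smallest adjusted p. Gene lists, comparisons, this rule and all alternatives but those named last below were fixed before the data were examined. The rule also named WRKY30, which the design text says was measured by qRT-PCR; no probe set carried that name in the annotation used, so it was not analysed here.

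Of the 26 pathway, hormone and tissue lists fixed in advance, with 447 members, 63 memberships were measured through a probe set with 1 gene, and 5 lists reached the minimum of 5 measured genes. These were early elicitor response, WRKY transcription factors, auxin response and transport, cell wall synthesis and remodelling, and class III peroxidases. Members of the shorter lists were read one by one. Because the annotation named so few members, 38 further lists, mostly gene families defined by symbol or locus, were written. This was done after the data had been seen and before any list was tested, and 36 of them had 5 or more measured genes. Some of them hold genes that the naming rule picks for their large changes, so their p-values are not independent of those genes. Lists were tested at gene level with limma's camera at a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the lists of each kind within a contrast. Camera with an estimated correlation and the self-contained test fry were run beside it.

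The same code was tested on simulated data built from the real means and residual spread, with 50 probe sets each changed by 0.5, 1, 1.5 or 2 on the log2 scale. For chitin against the control it recovered 60, 96, 98 and 94 percent of these, for cellobiose 62, 90, 98 and 100 percent, and for OGs 50, 96, 98 and 100 percent. Between elicitors it recovered 48, 96, 94 and 96 percent for OGs against chitin, 34, 96, 98 and 98 percent for OGs against cellobiose, and 62, 96, 98 and 100 percent for chitin against cellobiose. Calls on unchanged probe sets made up 4.57, 3.74, 5.18, 4.32, 4.47 and 6.12 percent of all simulated calls in these 6 comparisons. A simulated list of 20 genes shifted by 0.5 was called in each comparison and 0 of 20 unchanged lists were. The simulated genes varied independently of each other, so this does not test list calls where members are correlated. The correlation and covariance to be found by chance between the elicitor comparisons, which share the 3 control arrays, were estimated from 100 simulated sets of 12 unchanged arrays. Sign agreement with chitin was simulated in 100 further sets in which the chitin arrays carried the fitted changes of chitin's calls and the other groups were unchanged.

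Alternatives covered the replicate block, quantile normalization, centring each array on its median, a filter and a floor at log2 5, an intensity trend, array weights, fits on only the 2 groups compared, a minimum log2 change of 1, other set tests, and leaving out each array in turn. A covariate for RNA quality, a second form of the floor, the further lists and leaving out arrays for single named genes were added after the data had been seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.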

Results

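Root transcript levels were measured on 12 arrays, 3 for each of chitin oligomers, cellobiose, oligogalacturonides (OGs) and a control without elicitor. Chitin oligomers are chains of N-acetylglucosamine from fungal walls, cellobiose is the disaccharide unit of cellulose, and OGs are chains of galacturonic acid released from pectin. Arrays of the same group correlated at 0.992 to 0.997 across probe sets. No pair of arrays in a group was a copy, since at most 5 of the 22746 probe sets had identical values. The first principal component carried 39.3 percent of the variance and ran from the control arrays to the chitin arrays. OGs replicate 3 had a 3′ minus 5′ difference of 2.11 (log2) for the actin control probe sets, against 1.46 to 1.57 on the control arrays, and chitin replicate 2 had 1.15. For GAPDH the difference was 0.729 to 0.835 on the control arrays, 0.368 to 0.586 on the cellobiose arrays, 0.357 and 0.540 on OGs replicates 1 and 2 and 1.46 on OGs replicate 3. The polyadenylated spike-in transcripts averaged log2 6.12 to 6.31 on the control arrays and 6.21 on OGs replicate 3, against 5.82 to 5.99 on the other elicitor arrays. In a separate limma fit of the 64 control probe sets, 0 were called against the control after any elicitor. An unadjusted p under 0.05 was reached by 12 of them after chitin, 15 after cellobiose and 14 after OGs.

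Across the 4 groups, 2220 of 22746 probe sets (9.76 percent) changed by limma's moderated F test. The count was 1458 without chitin replicate 2.

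The comparison of chitin with the control asked which root transcripts a fungal wall fragment changes within 3 h. Among the genes the annotation names, which stand for 21 of the 50 largest increases, the largest included oxidases, chitinases and secreted peroxidases. AT1G26380, a berberine bridge enzyme-like oxidase of indole metabolism, went from log2 4.00 ± 0.13 to 9.32 ± 0.82 (SD, n = 3), an increase of at least 4.32 on the log2 scale (fitted 5.32 ± 0.29 SE, adjusted p = 1.25e-06), and its relative AT1G26420 rose at least 10.4-fold. Sizes of named genes are given as "at least" where the dimmer group's mean lay under log2 5, a level near background, which was then raised to 5. The chitinases AT2G43620 and CHI, enzymes that cleave chitin, rose 30.2-fold and 14.2-fold, the peroxidases AT3G03670 and AT5G39580 17.7-fold and 14.0-fold, and the lectin-like AT3G16530 17.1-fold. WRKY53, a transcription factor of defence and senescence, rose 12.9-fold (3.69 ± 0.16 SE, adjusted p = 3.60e-07). The remaining large increases were AT2G15220, a basic secretory protein whose probe set may also detect other sequences (20.2-fold), and the alpha/beta hydrolase AT2G39400 (at least 10.8-fold).

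The largest decreases after chitin included genes of photosynthesis and transport. PRK, the phosphoribulokinase of the Calvin cycle, fell by 2.49 ± 0.44 (SE, adjusted p = 0.00427), the antenna protein gene LHCB4.2 by 2.26 and the photosystem I subunit gene PSAN by 2.05. The amino acid transporter gene AT5G38820 changed by -2.07, the nitrate and peptide transporter family member AT2G26690 by -2.10, and the aldo-keto reductase gene AT5G62420 fell by at least 1.98. AT1G73120, AT3G61930, AT4G16980 and AT4G23680 completed this set, at -2.73, -2.45, -2.22 and -1.96. Leaving out each array in turn kept the call of 18 of the 20 genes. AT4G16980 lost it without control replicate 2 (adjusted p = 0.110), control replicate 3 (0.0772), chitin replicate 2 (0.108) or chitin replicate 3 (0.0602). AT4G23680 lost it without any of 5 arrays, with an adjusted p of up to 0.201 without control replicate 2. Without control replicate 1 these 2 log2 changes were -2.89 and -2.84, and without control replicate 3 AT3G03670 rose 26.9-fold.

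Of 9 measured genes of the early elicitor response 6 rose after chitin, among them WRKY53, the zinc finger repressor gene STZ (2.34), and PUB22 (1.15) and PUB23 (0.99), ubiquitin ligases that dampen immune signalling, while WRKY22 fell by 0.72. The list's median was 0.99 (camera adjusted p = 4.38e-08, and adjusted p = 0.0625 with an estimated correlation), and 8 members were called when adjusted over the list alone. Of 10 class III peroxidases, which act on phenolics and hydrogen peroxide in the wall, 7 rose and 0 fell, also 7 when adjusted over the list alone (adjusted p = 3.89e-09, and adjusted p = 0.0511 with an estimated correlation). Examples were AT5G39580 (3.80), AT1G14550, AT5G66390 (1.27) and AT5G64120 (0.69). Of 5 WRKY genes, WRKY53 and WRKY6 (0.74) rose and WRKY22 fell (adjusted p = 0.0154, and adjusted p = 0.0799 with an estimated correlation), with 4 called when adjusted over the list alone. WRKY53 and WRKY22 are also in the early elicitor list, so the results of these lists are not independent of each other.

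Of 5 cell wall synthesis and remodelling genes, the xyloglucan-modifying XTH19 (-0.67) and XTH26 fell and 0 rose, with 3 called when adjusted over the list alone (adjusted p = 0.0264, and adjusted p = 0.218 with an estimated correlation). That list was not called without control replicate 1 (adjusted p = 0.102) or chitin replicate 1 (0.133). Of 6 auxin genes, LBD16 (0.51) rose and GH3.1 (-0.46) fell, as they did when adjusted over the list alone, and the list was not called (adjusted p = 0.137). In lists too short to test, the tryptophan synthesis gene AT2G04400 rose by 1.45, the lignin synthesis gene CCR2 by 1.24, the malectin-domain receptor kinase gene AT1G56145 by 0.80, the salicylate-responsive glutaredoxin gene GRX480 by 0.69 and the receptor-associated kinase gene BIK1 by 0.45.

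The next lists were written after the data had been seen. The whole peroxidase family, berberine bridge enzyme-like oxidase, chitinase and nuclear photosynthesis lists among them hold genes named above. The p-values of these lists are therefore not independent of those genes. The whole class III peroxidase family had 15 of 55 genes higher and 3 lower, with a median of 0.06 (adjusted p = 0.000544, and adjusted p = 0.183 with an estimated correlation). Of these lists also, 7 of 15 chitinases rose and 0 fell, with AT2G43590 (2.92) and AT4G01700 (2.54) beside those named above (adjusted p = 9.60e-12, and adjusted p = 0.116 with an estimated correlation). Of 22 berberine bridge enzyme-like oxidases, 9 rose and AT4G20820 fell (adjusted p = 2.16e-07, and adjusted p = 0.0433 with an estimated correlation). All 12 measured nuclear photosynthesis genes fell, with a median of -1.65 (adjusted p = 2.95e-10, and adjusted p = 0.200 with an estimated correlation). The list's mean was log2 8.46, 8.71 and 9.17 on the control arrays, on which the spike-in transcripts were also brighter, and 7.64, 6.55 and 7.49 on the chitin arrays. None of the called lists changed direction under quantile normalization or median centring.

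In all, 2507 probe sets changed after chitin, 1157 up and 1350 down, and 548 of these by 2-fold or more. The largest increase had no gene in the annotation (5.54 ± 0.32 SE), nor had the largest decrease (-3.12 ± 0.30 SE). The majority of decreases turned under quantile normalization, which gave 1300 up and 1157 down. The count was 1540 without chitin replicate 2 and 1662 without control replicate 2, and 1088 when only these 2 groups were fitted.

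**Figure D1:**
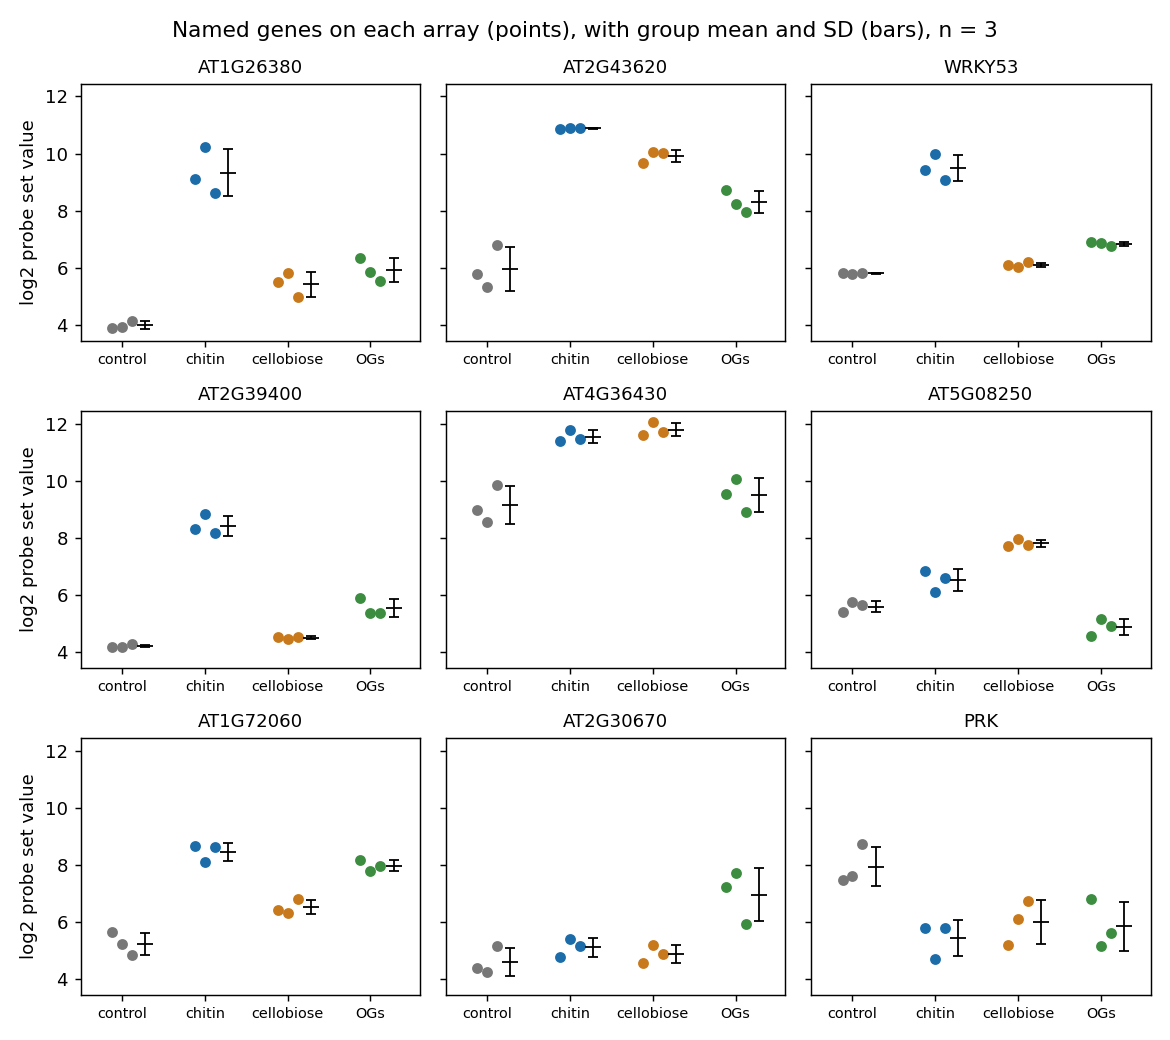
Log2 probe set values of 9 named genes on each of the 12 arrays (points, by group), with the group mean and SD as bars beside them (n = 3). AT1G26380, WRKY53 and AT2G39400 were highest after chitin, AT5G08250 was highest after cellobiose at 7.81 ± 0.12, and PRK was highest in the control at 7.94 ± 0.69.

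The comparison of cellobiose with the control asked the same question for a fragment of the plant's own cellulose. AT2G43620, the chitinase gene that chitin also raised, went from log2 5.96 ± 0.76 to 9.91 ± 0.22 (SD, n = 3), 15.5-fold (3.95 ± 0.30 SE, adjusted p = 8.82e-05). The peroxidase gene AT4G36430 rose 6.28-fold, the lipid transfer protein gene AT1G05450 at least 3.66-fold, the cytochrome P450 gene AT5G08250 4.65-fold, the laccase gene LAC16 4.39-fold, the lipase-like AT3G50400 4.18-fold and the peroxidase gene AT1G68850 3.83-fold. AT1G65500 (at least 4.35-fold), AT3G16530 (4.39-fold) and CHI (log2 change 1.96) completed the 10 largest increases.

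Decreases after cellobiose were smaller. The thylakoid protein gene CaS fell by 1.49 ± 0.29 (SE, adjusted p = 0.0265), LHCB4.1 by 1.15 and NdhS, of the chloroplast NADH dehydrogenase-like complex, by 1.11. AT5G38820 changed by -1.27, AT1G73120 by -1.70, AT5G62420 by -1.02, the anthocyanin glycosyltransferase gene UF3GT by -0.99, the cation efflux family member AT3G58060 by -0.98, AT1G04800 by -1.25 and AT1G04770 by -1.06. With each array left out in turn, 11 of the 20 genes kept the call throughout. The others were AT3G16530, with an adjusted p of 0.0503 without cellobiose replicate 2 and 0.0760 without replicate 3, and all decreases but AT5G38820 and NdhS. Every control and cellobiose array cost at least 1 of these genes its call when left out, and the highest of these adjusted p-values was 0.178, for UF3GT without cellobiose replicate 3.

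Of the 10 class III peroxidases, 4 rose after cellobiose and 0 fell, with AT4G36430 (2.65), AT5G39580 (1.76), AT5G66390 (0.85) and AT5G64120 (0.60), and 8 were called when adjusted over the list alone (adjusted p = 7.93e-06, and adjusted p = 0.129 with an estimated correlation). Of the 5 cell wall genes, ATPMEPCRB, which encodes a pectin methylesterase, fell by 0.85 and XTH19 by 0.54, and 3 were called when adjusted over the list alone (adjusted p = 0.000729, and adjusted p = 0.129 with an estimated correlation). Neither the 9 early elicitor genes (median 0.08, adjusted p = 0.604) nor the 5 WRKY genes (median -0.12, adjusted p = 0.604) were called, and limma called 0 members of either, also when adjusted over the list alone. WRKY53 stood at 0.29 ± 0.16 (SE, adjusted p = 0.406). LBD16 (0.46) was the member of the auxin list that rose, also when adjusted over the list alone, and that list was not called (median -0.06, mean 0.01, adjusted p = 0.945). In the shorter lists, AT2G04400 rose by 0.83 and AT1G56145 by 0.44.

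In the whole class III peroxidase family 8 of 55 genes rose after cellobiose and 1 fell, with a median of 0.04 (adjusted p = 0.0179, and adjusted p = 0.433 with an estimated correlation), a call lost without control replicate 1 (adjusted p = 0.0987) or cellobiose replicate 1 (0.147). Of the 15 chitinases 4 rose and 0 fell (adjusted p = 1.88e-08, and adjusted p = 0.212 with an estimated correlation). Of the 22 berberine bridge enzyme-like oxidases 4 rose and 1 fell (adjusted p = 0.00440, and adjusted p = 0.212 with an estimated correlation), a call lost without cellobiose replicate 1 (adjusted p = 0.0755). The 12 nuclear photosynthesis genes had a median of -1.19, with LHCB4.1 called and 11 when adjusted over the list alone (adjusted p = 1.61e-10, and adjusted p = 0.292 with an estimated correlation), and their mean was 7.21, 7.68 and 8.11 on the cellobiose arrays. The spike-in transcripts were again brighter on the control arrays.

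**Figure D2:**
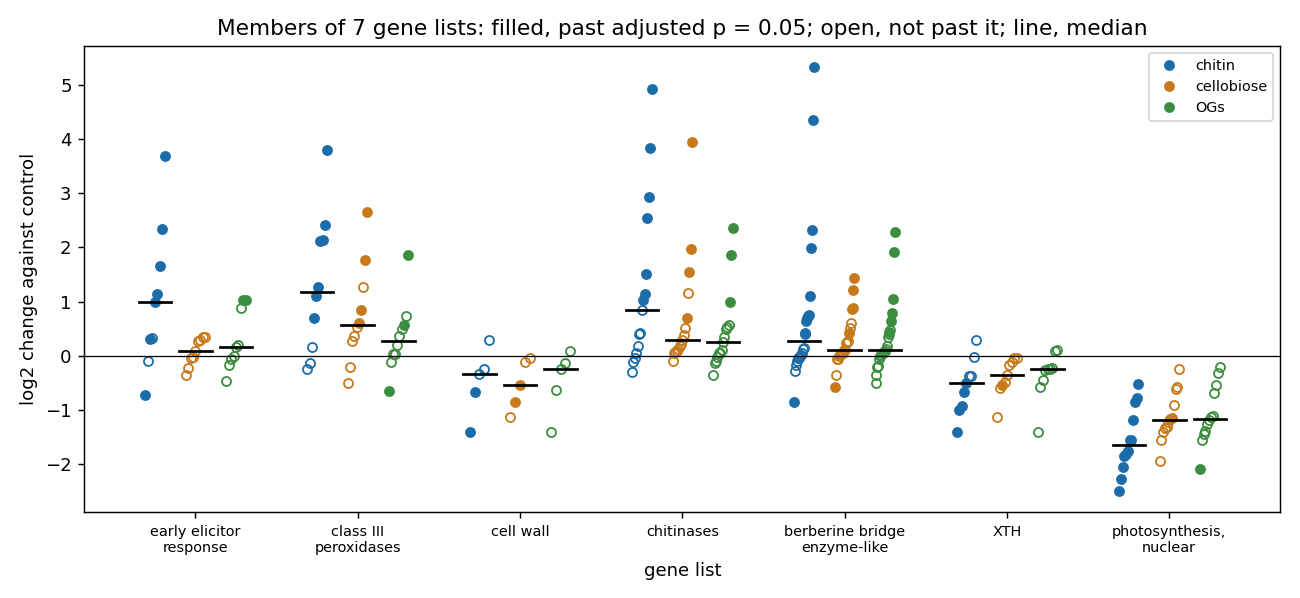
Log2 change against the control for each member of 7 gene lists after chitin, cellobiose and OGs (filled points passed an adjusted p of 0.05, lines are medians). The early elicitor list had its median at 0.99 after chitin and 0.08 after cellobiose, and the nuclear photosynthesis list at -1.65, -1.19 and -1.16 after the 3 elicitors.

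Cellobiose changed 516 probe sets, 351 up and 165 down, 126 of them by 2-fold or more. The probe set with the largest decrease had no gene in the annotation (fitted -2.02 ± 0.36 SE). Centring the arrays on their medians gave 292 up and 237 down. The count was 138 without cellobiose replicate 3, 223 without cellobiose replicate 1, 247 without cellobiose replicate 2 and 234 without control replicate 2.

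The comparison of OGs with the control asked the question for fragments of pectin. The protease inhibitor family gene AT1G72060 went from log2 5.24 ± 0.39 to 7.98 ± 0.18 (SD, n = 3), 6.67-fold (2.74 ± 0.18 SE, adjusted p = 0.000148). AT2G43620 rose 5.12-fold, AT1G26420 at least 2.48-fold, and cwINV6, named as a cell wall invertase, 4.21-fold. AT2G30670, of the tropinone reductase family, was at least 3.75-fold higher (adjusted p = 0.0105). The others were AT1G19530 (4.55-fold), AT1G22890 (4.41-fold), AT3G18250 (4.25-fold), AT5G22555 (at least 2.06-fold) and AT3G16530 (log2 change 1.96). The probe set with the largest increase had no gene in the annotation (fitted 3.80 ± 0.28 SE, from a control mean under log2 5). Nor had the one with the largest decrease (fitted -2.51 ± 0.36 SE).

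The sugar carrier genes SWEET13 and SWEET14 fell by at least 0.93 and by 1.03 after OGs, PRK by 2.08 ± 0.44 (SE, adjusted p = 0.0357), CaS by 1.43 and the pectin methylesterase inhibitor gene AT5G51520 by 1.13. AT3G61930 changed by -1.76, AT1G73120 by -1.74, AT5G62420 by -1.52, AT5G38820 by -1.22 and the lipid transfer protein-like AT4G33550 by -1.11. Leaving out each array in turn kept the call of 10 of the 20 genes. Every control and OGs array cost at least 1 gene its call when left out, in all AT2G30670, AT1G19530, AT3G16530, SWEET13, SWEET14, PRK, CaS, AT3G61930, AT1G73120 and AT5G51520, with a highest adjusted p of 0.154 for PRK without OGs replicate 2. Sizes moved by over 1.5 times for 3 genes. AT1G19530 went to 2.64-fold without control replicate 3. AT2G30670 went from a fitted 5.13-fold to 7.89-fold without OGs replicate 3, and PRK to a log2 change of -2.71 without OGs replicate 1.

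Auxin response and transport was a list called after OGs. The auxin-conjugating GH3.3 rose by 1.23 and LBD16, a regulator of lateral root initiation, by 0.48, and 3 of the 6 genes were called when adjusted over the list alone (adjusted p = 0.00153, and adjusted p = 0.188 with an estimated correlation). Of the 9 early elicitor genes, WRKY53 and STZ rose, both by 1.03, and 4 were called when adjusted over the list alone, 3 up and 1 down (adjusted p = 0.0262, and adjusted p = 0.337 with an estimated correlation). Of the 10 class III peroxidases AT5G39580 (1.86) and AT5G64120 (0.57) rose and AT4G26010 fell by 0.65, the same numbers as when adjusted over the list alone (adjusted p = 0.0239, and adjusted p = 0.321 with an estimated correlation). The 5 cell wall genes had a median of -0.24 with 0 called by limma and 2 when adjusted over the list alone (adjusted p = 0.0150, and adjusted p = 0.290 with an estimated correlation), and the 5 WRKY genes were not called (adjusted p = 0.361), with WRKY53 alone passing and 2 called when adjusted over the list alone.

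Of these OGs lists, only auxin was called with each array left out in turn. Without control replicate 1 the adjusted p was 0.0838 for the early elicitor and cell wall lists and 0.0628 for peroxidases. Without control replicate 2 it was 0.0576 for the early elicitor list and 0.194 for peroxidases, and without OGs replicate 1 it was 0.0712 and 0.0947. In the shorter lists AT1G56145 rose by 0.59 and AT2G04400 by 0.53.

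The whole class III peroxidase family was not called after OGs (4 of 55 genes higher, 3 lower, adjusted p = 0.940). The further list of 11 Aux/IAA and GH3 auxin response genes was not called with all arrays either (camera adjusted p = 0.0549). That auxin list was called without control replicate 3 (0.0188), OGs replicate 1 (0.0463) or OGs replicate 2 (0.0478). Of the 22 berberine bridge enzyme-like oxidases 6 rose after OGs and 0 fell (adjusted p = 7.22e-05, and adjusted p = 0.141 with an estimated correlation), and of the 15 chitinases 3 rose and 0 fell (adjusted p = 9.59e-05, and adjusted p = 0.343 with an estimated correlation). The 12 nuclear photosynthesis genes had a median of -1.16, with PRK called and 10 when adjusted over the list alone (adjusted p = 4.91e-09, and adjusted p = 0.343 with an estimated correlation). Their mean was 8.16, 7.32 and 7.64 on the OGs arrays, and the spike-in transcripts were brighter on the control arrays than on OGs replicates 1 and 2.

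OGs changed 603 probe sets, 366 up and 237 down, 134 of them by 2-fold or more. The count was 336 without OGs replicate 3, the array with the high 3′ signal, 250 without OGs replicate 1 and 280 without OGs replicate 2. It was 303 when only these 2 groups were fitted and 343 with array weights.

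**Figure D3:**
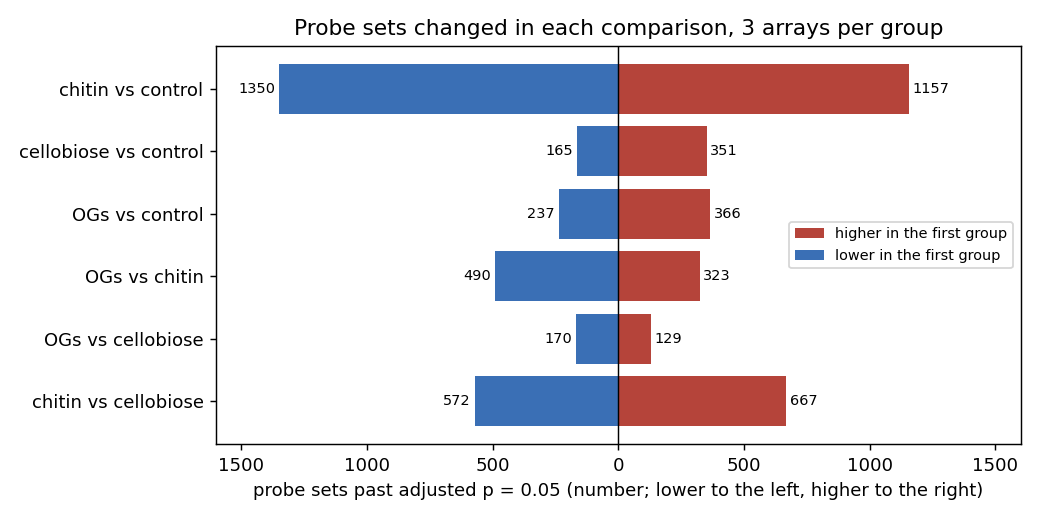
Number of probe sets past an adjusted p of 0.05 in each of the 6 comparisons, lower in the first group to the left and higher to the right. Chitin against the control gave 2507, cellobiose 516 and OGs 603.

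The elicitors were next compared with each other, at doses not given in the sources used here. OGs and chitin differed in 813 probe sets, 323 higher and 490 lower after OGs. AT1G26380 was lower after OGs by -3.41 ± 0.29 (SE, adjusted p = 9.25e-05), AT3G03670 by -2.96, AT1G49000 by -2.92, AT2G39400 by -2.88 and AT2G15220 by -2.75. AT1G19960 was 4.27-fold, AT2G30670 3.58-fold, the methyltransferase family gene AT5G38020 3.28-fold, the pectin methylesterase inhibitor gene AT1G62770 3.09-fold and AT3G59710 2.77-fold higher after OGs than after chitin. AT2G30670 lost the call without chitin replicate 1 (adjusted p = 0.0957), chitin replicate 2 (0.0805), OGs replicate 1 (0.106) or OGs replicate 2 (0.119). Without OGs replicate 3 it was 5.50-fold higher after OGs. Of the early elicitor genes 4 were lower after OGs and 0 higher (7 when adjusted over the list alone, adjusted p = 3.33e-10, and adjusted p = 0.0349 with an estimated correlation). Of the peroxidases 6 were lower (7 when adjusted over the list alone, adjusted p = 9.23e-11, and adjusted p = 0.0344 with an estimated correlation). Of the WRKY genes WRKY53 (-2.66) and WRKY6 (-0.62) were lower, both also when adjusted over the list alone (adjusted p = 0.00184, and adjusted p = 0.0349 with an estimated correlation). The auxin genes GH3.3 (0.92) and GH3.1 (0.43) were higher, with 3 called when adjusted over the list alone (adjusted p = 0.0247, and adjusted p = 0.171 with an estimated correlation). The count was 456 without chitin replicate 2, 503 without OGs replicate 2 and 485 without OGs replicate 3, and 187 with the actin 3′ minus 5′ difference as a covariate.

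OGs and cellobiose differed in 299 probe sets, 129 higher and 170 lower after OGs. Genes that cellobiose had raised were the lowest after OGs. AT5G08250 was at 4.88 ± 0.29 after OGs and 7.81 ± 0.12 after cellobiose (SD, n = 3; at least 2.77, fitted -2.94 ± 0.19 SE, adjusted p = 2.54e-05), AT1G68850 differed by -2.83, the lipid transfer protein gene AT5G13900 by -2.58, and LAC16 and AT1G05450 were lower by at least 2.54 and 1.87. Higher after OGs were AT2G30670 (at least 3.73-fold), AT1G19960 (3.20-fold), AT5G43450, of the oxoglutarate-dependent oxygenase family (3.07-fold), AT1G22890 (2.88-fold) and AT1G72060 (2.75-fold). AT2G30670 lost the call without any cellobiose array and without OGs replicates 1 or 2 (adjusted p up to 0.129, without cellobiose replicate 1), and it was 6.49-fold higher by the fitted change without OGs replicate 3. AT5G43450 lost it without cellobiose replicates 1 or 3 and OGs replicates 1 or 3 (up to 0.123, without OGs replicate 3).

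GH3.3 was higher after OGs than after cellobiose by 1.36, and 2 auxin genes were called when adjusted over the list alone (adjusted p = 0.000968, and adjusted p = 0.167 with an estimated correlation). AT4G36430 (-2.28) and AT5G66390 (-0.82) were the peroxidases that differed, also when adjusted over the list alone (adjusted p = 0.00454, and adjusted p = 0.184 with an estimated correlation). The early elicitor and WRKY lists had 0 members called by limma, 2 and 1 when adjusted over the list alone (adjusted p = 0.0354 for both, and adjusted p = 0.364 and 0.184 with an estimated correlation). Centring arrays on their medians kept the call of 2 of these 4 lists, and gave 186 probe sets higher and 146 lower. The count was 161, 153 and 167 without cellobiose replicates 1, 2 and 3, 171 without OGs replicate 1, 165 without OGs replicate 3 and 168 with the actin covariate.

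Chitin and cellobiose differed in 1239 probe sets, 667 higher and 572 lower after chitin. AT2G39400 was at least 10.8-fold (adjusted p = 1.11e-06), AT1G26380 14.9-fold, AT1G49000 at least 12.8-fold, WRKY53 10.5-fold and AT3G03670 9.22-fold higher after chitin. The dirigent family gene AT4G11190 was lower by -1.60, AT5G38020 by -1.53, AT3G59340 by -1.51, the glycosyltransferase gene UGT72B3 by -1.44 and AT1G62770 by -1.40. Of the 9 early elicitor genes 6 were higher after chitin, also when adjusted over the list alone (adjusted p = 2.23e-10, and adjusted p = 0.0332 with an estimated correlation). The WRKY list, which shares WRKY53 with that list, was also higher (2 genes, 3 when adjusted over the list alone, adjusted p = 0.000188, and adjusted p = 0.0332 with an estimated correlation). So were 3 peroxidases (5 when adjusted over the list alone, adjusted p = 5.32e-05, and adjusted p = 0.0726 with an estimated correlation). Centring arrays on their medians gave 846 higher and 316 lower. The count was 659 without chitin replicate 2, 625 without cellobiose replicate 2 and 667 without cellobiose replicate 3, and 2346 with array weights.

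For some genes raised by several elicitors the responses could not be separated. CHI differed between OGs and cellobiose by -0.11 (95 percent interval -0.43 to 0.22, adjusted p = 0.832) and AT5G39580 by 0.10 (-0.34 to 0.54, adjusted p = 0.896), while both were higher after chitin than after either. The peroxidase gene AT4G36430 differed between chitin and cellobiose by -0.24 (-0.97 to 0.48, adjusted p = 0.757), and cwINV6 between OGs and chitin by 0.05 (-0.46 to 0.57, adjusted p = 0.947).

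Calls of the 3 elicitors overlapped. Chitin and cellobiose shared 226 increases and 135 decreases, where independent lists of these lengths would share 17.9 and 9.79, and 1 probe set moved in opposite directions. Chitin and OGs shared 293 increases and 173 decreases, against 18.6 and 14.1, with 10 opposite. Cellobiose and OGs shared 127 and 63, against 5.65 and 1.72, with 16 opposite. All 3 elicitors raised 121 probe sets, among them those of AT2G43620, CHI, AT3G16530 and AT1G26420, and lowered 62. Chitin alone was past the threshold for 1860, cellobiose alone for 139 and OGs alone for 112.

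Because the comparisons share 3 control arrays, which are too few to split, part of this excess may come from those arrays. The covariance of log2 changes was 0.0594 for chitin and cellobiose, 0.0682 for chitin and OGs and 0.0386 for cellobiose and OGs, against simulated means of 0.00944, 0.0095 and 0.00949. Correlations across probe sets, which are not independent replicates, were 0.634, 0.714 and 0.624, against simulated medians of 0.498, 0.502 and 0.501. Of the 2507 probe sets called after chitin, 89.3 percent had the same sign after cellobiose and 92.9 percent after OGs, against 55.6 percent for both in simulations where only chitin changed. Those used the fitted chitin changes as true ones, which can understate the agreement that shared controls give.

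**Figure D4:**
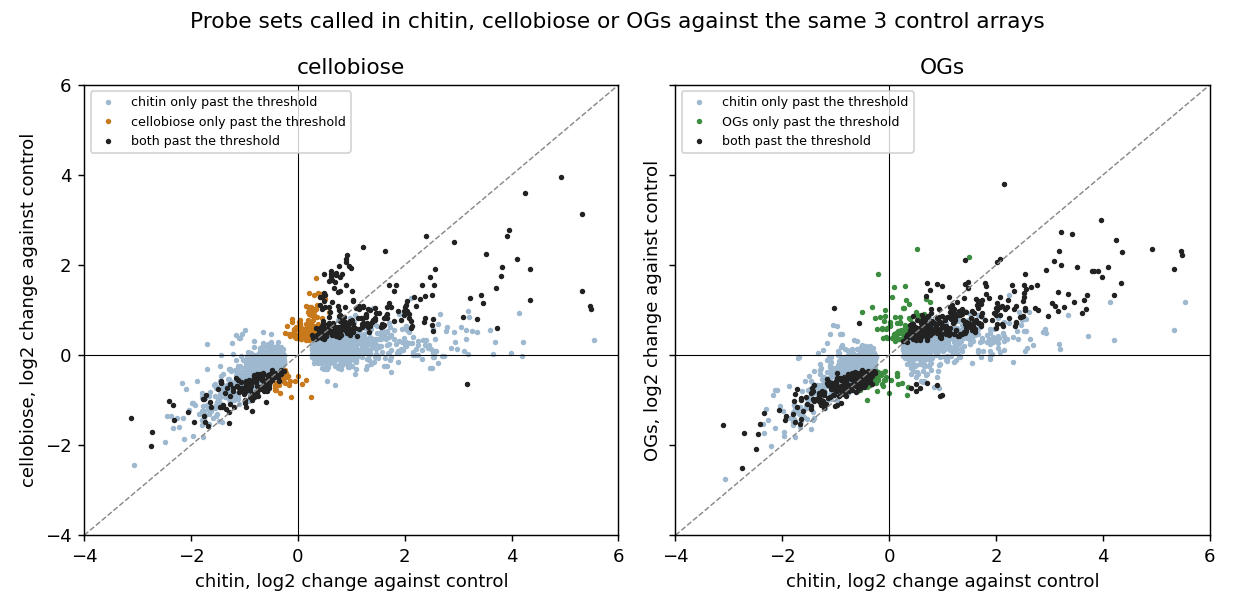
Log2 change against the control after cellobiose (left) or OGs (right) plotted against that after chitin, for probe sets called in either comparison, with a dashed line of equal change. Probe sets past the threshold in both (black) number 361 in the same direction on the left and 466 on the right.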

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

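The 3′ to 5′ signals below were looked at, and the covariate for them chosen, only after the array values had been seen; the regrouping tests were written beforehand.

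OGs replicate 3 carried a signal outside the comparisons above the level of the control arrays. The manufacturer's probe sets at the 3′ and 5′ ends of actin differed by 2.11 on it, against 1.46 to 1.57 on the controls. The difference was 1.46 for GAPDH, against 0.729 to 0.835 on the controls and 0.357 to 0.586 on the cellobiose arrays and other OGs arrays, and 1.31 for ubiquitin, against 1.02 to 1.13. Degraded RNA on this array as the only source of the calls of OGs against the control is excluded, since 336 probe sets changed without it. That was more than the 250 and 280 without OGs replicates 1 and 2. Whether this array made a part of the calls is undecided, since totals do not show which calls rest on 1 array. Of the 603 calls 275 remained without it, 212 and 247 without the others, and with the actin difference as a covariate 404 probe sets changed, 312 of them shared. Whether it hides calls is undecided. The count without it was 0.557 of that with all arrays, which met the criterion written for no hidden calls. Leaving out any OGs array lowers the count, however, so that criterion could not tell the cases apart and was not applied. For OGs against chitin and against cellobiose neither was tested, and leaving this array out gave 485 and 165 probe sets, the lowest of the OGs arrays. No biological explanation was tested.

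Regrouping the 6 arrays of a comparison into every other 3 and 3 asked whether chance assignment gives as many calls. For chitin against the control 1 of 10 splits, the real one, reached 2507 probe sets, and the highest other gave 0. The same held for cellobiose (1 of 10, real 516, highest other 0), OGs (1 of 10, real 603, highest other 0), OGs against chitin (1 of 10, real 813, highest other 0), OGs against cellobiose (1 of 10, real 299, highest other 0) and chitin against cellobiose (1 of 10, real 1239, highest other 0). For gene lists fixed in advance, 2 of 10 splits reached the real 4 for chitin (highest other 4), 3 of 10 the real 2 for cellobiose (highest other 3) and 1 of 10 the real 4 for OGs (highest other 1). With 10 splits no share under 0.05 is possible, so these tests leave chance undecided. Of 100 groupings of the 12 arrays, the real one and random others, only the real one reached the 2220 probe sets of the F test. The highest other gave 15. That share lies under 0.05, which makes chance an unlikely source of that count.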

How the results depend on the processing

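The actin covariate, the second form of the floor, the further lists and the single-array tests of named genes were chosen only after the data had been seen. No named gene changed direction with either floor, without the block, under quantile normalization or without an array, and no list called against the control without the block or an array, with the brightness filter, under the other scalings or in the other set tests. Lists called between elicitors kept their direction under the other scalings and set tests, and the remaining alternatives were run for counts only. The balance of calls did turn, from 1157 up and 1350 down to 1300 and 1157 after chitin under quantile normalization, and from 129 and 170 to 186 and 146 for OGs against cellobiose under median centring. Totals of changed probe sets stayed within 1.5 times their value under quantile normalization, median centring, the brightness filter and the intensity trend.

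With values under log2 5 raised to 5, the counts were 1408 for chitin, 155 for cellobiose, 110 for OGs, 323 for OGs against chitin, 118 for OGs against cellobiose, 585 for chitin against cellobiose and 856 for probe sets changed between any groups. That floor makes 7162 probe sets constant and lowers limma's prior degrees of freedom from 4.55 to 0.361; 38 of 90 named gene results lost their call, and 9 of 90 once those probe sets were left out. With a log2 change of at least 1 also required, which by construction can only remove calls, the counts were 548, 126, 134, 227, 115, 269 and 583 in the same order, and the overlaps 139 for at least 2 elicitors, 72 for chitin and cellobiose, 110 for chitin and OGs and 47 for cellobiose and OGs. Fitting only the 2 groups compared gave 1088 for chitin and 303 for OGs, and 714 for cellobiose, 646 for OGs against chitin, 360 for OGs against cellobiose and 1418 for chitin against cellobiose. Array weights gave 343 for OGs and 2346 for chitin against cellobiose, and the actin covariate 187 for OGs against chitin and 168 for OGs against cellobiose; for these and for the fits of 2 groups the cause was not tested.

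Leaving out each array in turn, which tests fewer samples, gave 1540 to 2640 for chitin, 138 to 583 for cellobiose, 250 to 425 for OGs, 456 to 834 for OGs against chitin, 153 to 227 for OGs against cellobiose, 625 to 1200 for chitin against cellobiose and 1458 to 2327 for the F test. Of 540 such values of named genes 448 kept the call and 92 lost it. Under quantile normalization 1 of 90 lost it, AT4G23680 after chitin.

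Of the 5 lists fixed in advance, 4 were called for chitin, 2 for cellobiose and 4 for OGs. With an estimated correlation these were 0, 0 and 0, and with fry OGs had 1; the cause was not tested. With dim probe sets removed they were 2, 1 and 2, because only 2 lists kept 5 genes. Leaving out arrays gave 3 to 4, 2 to 2 and 1 to 4. Of the further lists 15, 11 and 11 were called, 1, 0 and 0 with an estimated correlation, and 5 and 5 with fry for cellobiose and OGs. Leaving out arrays gave 13 to 15, 8 to 12 and 6 to 12.

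Without the replicate block the counts were 2698, 611 and 676 for chitin, cellobiose and OGs, 961 for OGs against chitin, 372 for OGs against cellobiose, 1433 for chitin against cellobiose and 2548 for probe sets changed between any groups. No call of a named gene changed, nor of a list against the control. Of 18 pairs of arrays with the same number 6 correlated over 0.1 after group means were removed (-0.23 to 0.25), and 4 of 12 arrays correlated best with their own number, a hint from the data, not the design, that the numbers carry little shared signal. The tests named for WRKY30 were not run. Dim signal limits what could be seen, since 35.6 percent of values lay under log2 5.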

Other observations

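The further gene lists, the green tissue test and the suberin list were written only after the annotation or the named genes had been seen; the suberin list was written before its 6 genes were tested.

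Of 11 extensins, structural proteins of the wall, 3 rose and 2 fell after chitin and the list was not called (adjusted p = 0.712). AT1G26250 rose by 3.46, and also after cellobiose (1.17) and OGs (1.18). AT4G20830, which encodes an oxidase of OGs, rose after chitin (1.99), OGs (1.05) and cellobiose (0.89). AT4G20860, which encodes an oxidase of cellodextrins, rose 2.14-fold after chitin. Its log2 change was 0.11 after cellobiose (adjusted p = 0.680) and 0.48 after OGs (adjusted p = 0.0570). Of 7 calmodulin-like genes 3 rose after chitin and 0 fell (adjusted p = 0.000613, and adjusted p = 0.183 with an estimated correlation). Of 7 defensins 1, PDF1.4, rose by 1.53 after OGs and 2 fell, and the list was not called (adjusted p = 0.430).

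Of 9 xyloglucan-modifying XTH genes 5 fell after chitin and 0 rose, with XTH32 at -0.93 (adjusted p = 0.000613, and adjusted p = 0.200 with an estimated correlation), and of 14 expansins 4 fell and 0 rose (adjusted p = 0.0254, and adjusted p = 0.183 with an estimated correlation). Of 8 histone genes 2 fell after OGs, with HTB2 at -0.59 (adjusted p = 2.95e-06, and adjusted p = 0.141 with an estimated correlation). The XTH and expansin lists were also called after OGs (camera adjusted p = 0.0065 and 0.0279), and the histone list after chitin (0.0125). Each of these further calls was lost when certain single arrays were left out, and none held with an estimated correlation. SWEET13 and SWEET14, which fell after OGs, also fell after chitin, where they were the 2 of 15 sugar carriers of that family to change and the list was not called (adjusted p = 0.272).

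The nuclear photosynthesis list was lower after each elicitor at the preset correlation but not with an estimated correlation (adjusted p = 0.200, 0.292 and 0.343), with 12, 1 and 1 of 12 genes called (12, 11 and 10 when adjusted over the list alone). Spike-in transcripts were brighter on the control arrays than on all elicitor arrays but OGs replicate 3. A single control array as the source is excluded, since the lowest ratio of the list's median without a control array to that with all arrays was 0.831. Green shoot tissue in the control samples is undecided. Plastid-encoded genes moved at most 0.265 times as far as the nuclear list, with medians of -0.28, -0.32 and -0.25 after chitin, cellobiose and OGs. Their list was called after chitin (camera adjusted p = 4.61e-05) and OGs (camera adjusted p = 2.72e-05). Those calls were lost without chitin replicate 3 (0.306) or OGs replicate 1 (0.130), and with an estimated correlation. Plastid-encoded genes also have a baseline in roots (mean log2 7.76 after elicitors) that could hide a small share of green tissue. The criterion was revised once this value had been seen. A change of the nuclear photosynthesis genes within 3 h of treatment was not tested apart from green tissue.

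Hypothesis: cellobiose and OGs move suberin-related genes in opposite directions. The named genes AT5G08250, AT1G05450 and AT3G50400 are of families that act in suberin, so 6 other genes linked to it were tested. All 6 lay above 0 after cellobiose, 3 of them called, with a median of 0.70 (limma's fry gave 8.84e-05 unadjusted, and adjusted p = 0.000265 over the 6 comparisons), and AT1G74460, AT3G22620 (1.03) and AT2G48130 (0.78) rose. All 6 were lower after OGs than after cellobiose, 4 called, with a median of -1.06 (fry 1.00e-05 unadjusted, adjusted p = 6.02e-05), while against the control OGs had a median of -0.35 with 1 called (adjusted p = 0.00686). Both predictions were met, but both would also hold if cellobiose alone raised these genes. All 6 were lower after chitin than after cellobiose too (median -0.61, fry adjusted p = 0.000941), while chitin against the control had a median of 0.26. Only OGs against the control bears on a fall, and there AT5G08250, AT1G05450 and AT3G50400 were not called (-0.72, -0.14 and -0.34). The other genes with the largest decreases in OGs against cellobiose were AT5G13900, AT1G68850 and LAC16. Against the control, AT5G13900 (-0.88, limma adjusted p = 0.0283) and AT1G68850 (-0.89, 0.0349) were called after OGs and LAC16 (-0.49) was not. A link of these genes to suberin was not tested. The 6 genes also share arrays with those that prompted the list, so the test is not independent of them.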
